A study of Mus musculus with 4 samples.

How the data were processed

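The series measured RNA levels in R1 mouse embryonic stem cells, an established mouse cell line, after infection with a lentivirus carrying a short hairpin RNA (shRNA). Per the labels, 2 samples received an shRNA against Brg1, the ATPase of the SWI/SNF chromatin remodelling complexes that is encoded by Smarca4. The other 2 received an shRNA against the glucose transporter GLUT4 (Slc2a4) as the control. Per the labels' protocols, cells were harvested 67 h after infection, RNA was extracted with Trizol, and biotin-labelled RNA was made with a transcript labelling kit. Each sample was read on 1 Affymetrix array.

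The deposited values are one intensity per probe set and array on a linear scale, and per the submitters' processing notes they came from the Affymetrix software GCOS. The version of GCOS, its signal algorithm and its scaling target are not given in the sources used here. From the values themselves, the mean after leaving out 2% of the probe sets at each end was 200.1 on all 4 arrays, so each array had been scaled to one common level before deposit. Detection calls and scanner files were not used here, and no probe set is called absent or present. The table held 22690 probe sets, of which 64 were Affymetrix control probe sets. Of the rest, 20380 had 1 gene in the platform annotation, 691 had several and 1555 had none. Gene symbols were updated by Entrez ID through the RefSeq gene table of assembly GRCm38.p6, which held 20351 of the 20380; the other 29 kept the symbol of the annotation. No genome build is part of these values, so no coordinates are given. All sample columns of the table were used.

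The signals were analysed as log2(signal + 20.0), where the pseudocount of 20.0 signal units is 10% of the mean trimmed mean, with no further normalization. Differences and folds are on this scale, which understates the change of dim genes. Of several probe sets of a gene, the one with the highest mean log2 value over the 4 arrays was used, and probe sets ending in _x_at only where a gene had no other. This gave 12393 genes, of which 7815 lay at or above the 40th percentile of all probe sets that are not controls (23.9 signal units) and were tested. Knockdown and control were compared with limma (version 3.58.1 in R 4.3.3), with lmFit and then eBayes with an intensity trend, two-sided. The p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The adjusted p of a single gene comes from this limma fit, except where the text names an alternative or a further probe set. Those of further probe sets come from a limma fit of every probe set by itself. A second count used no test: genes with a difference of 2-fold or more whose 2 knockdown arrays both lay above or both below the 2 control arrays.

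There were 20 gene lists, for SWI/SNF subunits, pluripotency, LIF and STAT3 targets, Nodal and BMP targets, FGF and ERK targets, primitive endoderm, trophectoderm, primitive streak and mesoderm, neuroectoderm, Hox genes, germline genes, mitosis, DNA replication, p53 targets and cell cycle inhibitors, interferon response, fibroblast markers, cholesterol synthesis, glycolysis and hypoxia, stress and the unfolded protein response, and DNA methylation and Polycomb. The 18 lists with at least 5 tested members were tested with camera (limma), which asks whether a list's genes differ from the other tested genes, with its preset correlation of 0.01 and adjustment over the 18 lists. Beside it stand camera with a correlation estimated from the data and fry, whose directional p tests whether a list's genes move one way on balance. Neither fry p compares a list with other genes. Some genes belong to several lists, so the list results are not independent of each other. With 2 arrays per group, camera with an estimated correlation has few residual degrees of freedom. Its smallest p over the 18 lists was 0.0328 before adjustment. A call lost there may reflect low power, or a preset correlation of 0.01 that is too small for genes that move together. These readings were not told apart. The named genes are the 2 shRNA targets, the 10 largest rises and 10 largest falls among genes past the test whose arrays did not overlap between the groups, and from each list up to 4 tested members with the smallest p. Genes outside this rule are said to have been chosen after their values were seen. The groups, main test, lists, naming rule and most alternatives were fixed before the data were examined.

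The alternatives changed the pseudocount, the filter, the normalization between arrays, the variance model, the choice of probe set, the threshold, the fold, the set test and the use of the replicate number as a block, and left out each array in turn. Where an array is left out, 1 group has a single array, which is then assumed to vary like the other group. A crossed replicate block and a scaling of each array to its hybridisation spike-ins were added after seeing the data. The model was tested on simulated data for the 7815 genes tested in the comparison of Brg1 knockdown with control shRNA. The gene means were real, while the spread was drawn from the fit's own variance model and the noise was independent between genes. The model recovered 92% of 100 genes changed 2-fold and 41% of 100 genes changed 1.41-fold, and 7.33% of its calls were unchanged genes. A smaller share of genes was changed than the 14.4% called in the data, so these rates need not hold for the data.

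With 2 arrays per group, the number of arrays limits the precision. The design text calls the infections duplicates and does not say how far they were handled separately, so the p-values measure only the spread between these samples, which may be technical in part. There is 1 hairpin per target, so effects of the Brg1 hairpin on other genes cannot be separated from those of lower Brg1 levels.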

Results

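Expression was measured on 4 Affymetrix arrays, 2 from R1 mouse embryonic stem cells with an shRNA against Brg1 and 2 from the same cells with a control shRNA against GLUT4, all harvested 67 h after infection. The series is about Brd7 as a subunit of PBAF, one form of the SWI/SNF complex. This part of it asks which genes change when Brg1, the ATPase of the complex, is knocked down. The arrays had a common scale, with a trimmed mean of 200.1 signal units each. Median signals were 49.5 and 50.1 on the knockdown arrays and 46.6 and 48.2 on the control arrays. The ratio of the 3' to the 5' probe set, a measure of RNA integrity, was 1.36 and 1.31 for beta-actin on the knockdown arrays and likewise 1.36 and 1.31 on the control arrays. For Gapdh it was 0.834 and 0.827 against 0.843 and 0.845. Over the tested genes, the SD of the log2 differences was 0.22 between the knockdown arrays and 0.20 between the control arrays, against 0.32 to 0.38 between arrays of different groups.

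The arrays measured RNA only, not Brg1 protein. Smarca4, which encodes Brg1, fell in part in the knockdown. Its signal was 636.8 ± 21.6 (SD, n = 2) against 1200.1 ± 19.09 (SD, n = 2) in the control. That is a log2 difference of -0.89 ± 0.08 (SE), or 1.86-fold on the scale with the pseudocount (limma, adjusted p = 0.000232). A second probe set of the gene gave 80.2 ± 6.36 against 160.0 ± 2.19 (SD), a log2 difference of -0.85. Slc2a4, the target of the control shRNA, lay below the filter and was not tested, with 22.4 ± 2.12 in the knockdown and 15.5 ± 5.30 in the control (SD, n = 2 each).

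Among the other SWI/SNF subunits, Brd7 fell from 510.5 ± 7.92 to 372.6 ± 52.3 (SD, n = 2 each), a log2 difference of -0.44 ± 0.11 (SE; limma, adjusted p = 0.0264). Arid1a, the DNA-binding subunit of the BAF form, rose by 0.37 ± 0.07 on the log2 scale (adjusted p = 0.00925). Of the 18 tested subunits, 3 rose, 3 fell and 12 did not pass the test. Adjusted over the list alone, 4 rose and 3 fell. The list median was 0.01, the mean was -0.01 and camera's direction was down (adjusted p = 0.71), so median and mean differed in sign. Ss18 (0.32) and Smarcd3 (0.66) were the other rises and Smarce1 (-0.32) the other fall, the last 2 chosen after their values were seen. The call of Brd7 was lost without knockdown replicate 2 (adjusted p = 0.146) and without control replicate 1 (adjusted p = 0.0559). Smarce1 lost its call without each array in turn, and Ss18 and Smarcd3 lost theirs without knockdown replicate 2 or control replicate 1. Ss18 also lost its call without control replicate 2, and Smarcd3 without knockdown replicate 1.

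**Figure D1:**
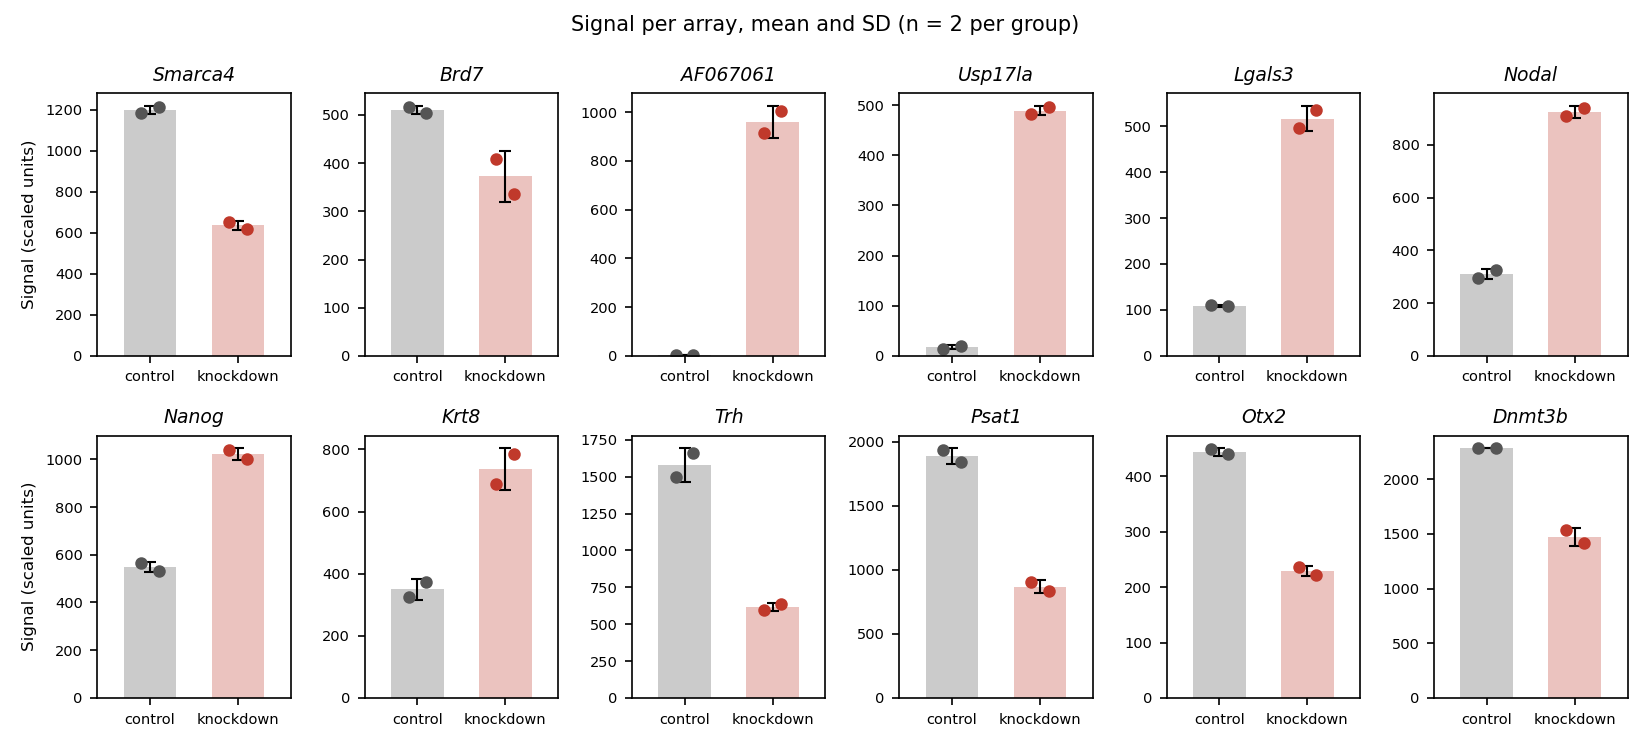
Signal (linear units) of 12 genes on each array, with bars for the mean of the 2 arrays per group, error bars for the SD and points for single arrays. Smarca4 lies at 636.8 in the knockdown and 1200.1 in the control, and AF067061 at 960.4 and 3.40.

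Of the 7815 genes tested, 1127 (14.4%) changed with limma at an adjusted p under 0.05, 729 higher and 398 lower in the knockdown. With each array centred on its median, 622 were higher and 598 lower, so the excess of rises depends on the scaling. In 85 genes the difference was 2-fold or more with no overlap between the groups, 76 higher and 9 lower, and all 85 also passed the test. Of all 7815 tested genes, 60.2% had both knockdown arrays on the same side of both control arrays, which chance gives for 33.3% of unchanged genes. The count was 601 without knockdown replicate 2 and 719 without control replicate 1.

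The hybridisation spike-ins, bacterial and phage transcripts added at the hybridisation step, averaged 9.37 on the log2 scale in the knockdown and 9.68 in the control. Added at that step, they do not measure the RNA content of the cells. Scaling the arrays to them moved the median log2 difference of all tested genes from 0.04 to 0.33. Directions of change are therefore relative to the deposited scale; of the 398 falls, 345 stayed below 0 with this scaling. Of the 34 falls among the named genes, 29 stayed below 0, and Birc5, Idi1, Ldha, Nusap1 and Top2a did not. Among the named genes that lost their call with this scaling were Brd7 (adjusted p = 0.686), Dnmt3b (0.25), Dnmt3a (0.156), Otx2 (0.0504), Tk1 (0.455), Irf1 (0.375), Fn1 (0.18), Pfkp (0.14), Atf4 (0.24), Asns (0.43) and Lefty1 (0.461), while Smarca4 kept it (0.046). The median of each of the 20 lists lay above 0 with the spike-in scaling.

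The 2 largest rises, AF067061 and Usp17la, started from control signals below the filter level of 23.9, so their size depends on the pseudocount. AF067061 rose from 3.40 on both control arrays to 960.4 ± 65.1 (SD, n = 2), a log2 difference of 5.39 ± 0.12 (SE; limma, adjusted p = 1.16e-08). Usp17la, a gene of the Usp17 family of deubiquitinases, rose from 17.5 ± 4.38 to 488.8 ± 9.33 (SD), a log2 difference of 3.77 ± 0.13 (adjusted p = 4.25e-07). With the smaller and the larger pseudocount the differences were 6.84 and 4.24 for AF067061 and 4.47 and 2.998 for Usp17la. Each rests on a single probe set, and the probe set of AF067061 is of a kind that can bind several transcripts. The neuroendocrine transcription factor gene Insm1 rose by 2.01 on the log2 scale, the galectin gene Lgals3 by 2.06 and Lix1 by 2.13. Marveld1 (1.99), Msln (1.93), Nkx2-9 (1.66), Rnf128 (1.63) and Morc1 (1.63) complete the 10 largest rises by this measure. Lix1, Msln and Nkx2-9 also had control signals below the filter level (18.45, 3.40 and 11.25), so their sizes and ranks depend on the pseudocount too, and with the larger one they rose by 1.52, 1.16 and 1.04. The rises of Foxa2, Fosl1 and Smarcd3 also started below that level.

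The largest falls included 2610528J11Rik (log2 difference -1.53), Mpzl2 (-1.39), Dpys (-1.26), Acot1 (-1.08) and Anxa6 (-1.07), and Fam111a, at 133.5 against 286.1 signal units. Other Mpzl2 probe sets above the filter gave only -0.23 and -0.52 (adjusted p = 0.285 and 0.0732 with every probe set tested by itself). The size and rank of its fall therefore depend on the probe set. Trh, which encodes the precursor of thyrotropin-releasing hormone, fell from 1579 ± 115.6 to 615.9 ± 28.6 (SD, n = 2 each), a log2 difference of -1.33 ± 0.09 (SE; limma, adjusted p = 3.49e-05). Psat1, an enzyme of serine synthesis, fell from 1889 ± 62.6 to 868.6 ± 50.4 (SD), a difference of -1.10 ± 0.08 (SE; adjusted p = 5.95e-05). Pck2, the mitochondrial PEP carboxykinase, fell by 1.11, and Chac1, which degrades glutathione, fell by 1.25 on the log2 scale.

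**Figure D2:**
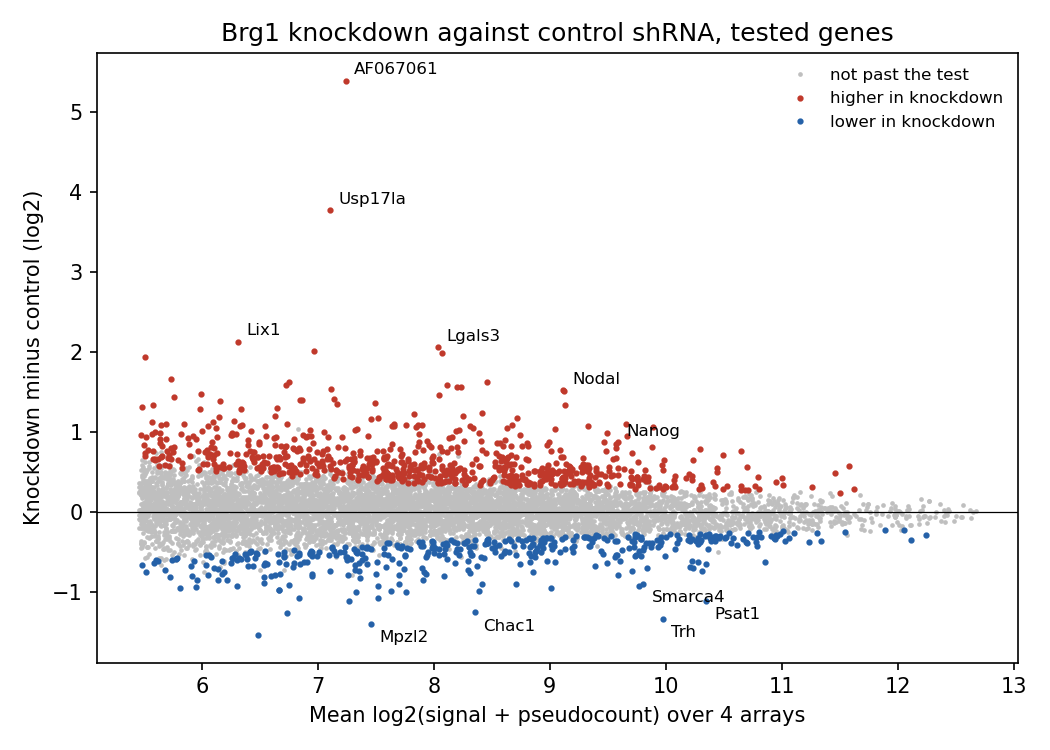
Log2 difference (knockdown minus control) against the mean log2 signal with the pseudocount for the 7815 tested genes, with red and blue points for the 729 genes higher and the 398 lower in the knockdown at an adjusted p under 0.05. AF067061 and Usp17la lie apart from the other genes, at 5.39 and 3.77.

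Genes of the pluripotency network rose more often than they fell. Nanog, a core pluripotency factor, rose from 549.2 ± 22.0 to 1022 ± 26.1 (SD, n = 2 each), a log2 difference of 0.87 ± 0.08 (SE; limma, adjusted p = 0.000299). Klf2 (0.76 ± 0.09) and Dppa2 (0.71 ± 0.07) also rose, while the DNA methyltransferase gene Dnmt3b fell by 0.63 ± 0.07. Of 31 tested members, 12 rose, 3 fell and 16 did not pass the test, and 15 rose and 3 fell adjusted over the list alone. Pou5f1 and Sox2, chosen after their values were seen, had log2 differences of 0.01 ± 0.07 (adjusted p = 0.95) and -0.22 ± 0.09 (adjusted p = 0.125). The list rose with camera (median log2 difference 0.20, adjusted p = 0.0191). Its call was lost with adjusted p = 0.431 with an estimated correlation, 0.0653 without the intensity trend and 0.0796 without knockdown replicate 1.

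Targets of LIF and STAT3, the pathway that maintains mouse ES cells in culture, gave 5 rises and 0 falls in 16 tested members, with 11 not past the test and the same 5 and 0 adjusted over the list alone. Myc (log2 difference 0.68 ± 0.10), Klf4 (0.76 ± 0.13) and Tfcp2l1 (0.88 ± 0.14) rose, with limma's adjusted p between 0.00219 and 0.00554. Klf4 and Tfcp2l1 are also in the pluripotency list and Myc in the FGF and ERK list, so these rises are counted again there. Icam1 rose by 0.52 ± 0.12 (limma, adjusted p = 0.0191). It lost its call without knockdown replicate 2 or control replicate 1, where its log2 difference was 0.45 and 0.46. With the mean of all probe sets, Tfcp2l1 no longer passed (adjusted p = 0.0705). The list rose with camera (median 0.18, adjusted p = 0.0441). That call was lost with adjusted p = 0.467 with an estimated correlation, 0.0617 with the stricter filter, 0.0729 without the intensity trend, 0.109 with fry, 0.129 without knockdown replicate 1 and 0.212 without control replicate 1.

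Both de novo DNA methyltransferase genes fell. Dnmt3a fell by 0.73 ± 0.09 on the log2 scale (SE; limma, adjusted p = 0.00124), although 1 dim probe set of the gene differed in sign, at 0.23 (adjusted p = 0.41 with every probe set tested by itself). Bmi1, a Polycomb gene, rose by 0.93 ± 0.14. Dnmt3l, the other rise of the list, rose by 0.31 ± 0.08 (limma, adjusted p = 0.0359). It lost its call without knockdown replicate 2 or control replicate 1, where its log2 difference was 0.27 and 0.26. Among 24 tested DNA methylation and Polycomb genes, 2 rose, 2 fell and 20 did not pass. Adjusted over the list alone, 3 rose and 2 fell. Camera gave an adjusted p of 0.555 for this list (median 0.11).

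Nodal had the largest rise of the Nodal and BMP target list. It rose from 310.6 ± 19.0 to 925.0 ± 22.8 (SD, n = 2 each), a log2 difference of 1.52 ± 0.09 (SE; limma, adjusted p = 2.53e-05). Id1 (0.84 ± 0.09), Id2 (0.78 ± 0.11) and Msx1 (1.07 ± 0.15), known as BMP targets, also rose. Lefty1, a Nodal antagonist and target chosen after its values were seen, fell by 0.54 ± 0.08 (adjusted p = 0.00376). Of 11 tested members, 6 rose, 1 fell and 4 did not pass, with the same 6 and 1 adjusted over the list alone. The list rose with camera (median 0.66, adjusted p = 0.0191). The call was lost with adjusted p = 0.431 with an estimated correlation, 0.264 with the stricter filter and 0.0796 without knockdown replicate 1.

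Among FGF and ERK targets, Phlda1 rose by 1.35 ± 0.13 and Dusp6, a phosphatase of ERK, by 0.62 ± 0.08 on the log2 scale (limma, adjusted p = 0.000319 and 0.00134). Of 15 tested members, 4 rose, 0 fell and 11 did not pass, with the same 4 and 0 adjusted over the list alone. Myc and Fosl1 were the other rises, and Fosl1 lost its call without knockdown replicate 2 (adjusted p = 0.195), control replicate 1 (0.224) or control replicate 2 (0.0526). The list did not pass camera (median 0.25, adjusted p = 0.0585). It passed with the replicate block (adjusted p = 0.043), with median centring, with the mean of all probe sets, with the spike-in scaling, and without knockdown replicate 2 (0.0158) or control replicate 2 (0.00725).

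Of 13 tested trophectoderm genes, 6 rose, 0 fell and 7 did not pass the test, with the same 6 and 0 adjusted over the list alone. Krt8, a keratin of simple epithelia, rose from 349.2 ± 32.6 to 737.6 ± 67.2 (SD, n = 2 each), a log2 difference of 1.04 ± 0.10 (SE; limma, adjusted p = 0.000376). Tfap2c, a transcription factor of trophoblast, rose by 0.93 ± 0.17 and Elf3 by 0.64 ± 0.12. Id2, which is also in the Nodal and BMP list, was another of the rises. The list median was 0.39 and camera gave an adjusted p of 0.00868, against 0.431 with an estimated correlation and 0.146 when genes below the filter were included.

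Primitive endoderm genes moved both ways. Apoe rose by 0.79 ± 0.09 (limma, adjusted p = 0.000628), and Lama1, a laminin chain of basement membrane, fell by 0.55 ± 0.13 on the log2 scale. The call of Lama1 was lost without knockdown replicate 1 (adjusted p = 0.064) or control replicate 2 (0.0969). Foxa2 (0.94) and Sparc (0.43) also rose, and lost their calls without knockdown replicate 2 (0.0553 and 0.213) or control replicate 1 (0.0663 and 0.187). Of 11 tested members, 3 rose, 1 fell and 7 did not pass, with 4 and 1 adjusted over the list alone. The list did not pass camera (median 0.04, adjusted p = 0.532). Of 31 primitive streak and mesoderm genes on the array only 2 reached the filter, Tal1 (log2 difference -0.51, adjusted p = 0.0729) and Eomes (0.32, adjusted p = 0.236). Neither passed over all genes, and 1 was lower adjusted over the list alone. Of 31 Hox genes, Hoxa5 alone reached the filter, and it rose from 9.95 ± 2.19, below the filter level, to 55.9 ± 5.09 (SD), a log2 difference of 1.34 ± 0.17 (adjusted p = 0.00129), and of 2.03 or 0.82 with the smaller or larger pseudocount. Neither list was tested with camera.

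Neuroectoderm genes fell more often than they rose. Otx2, a transcription factor of the epiblast and anterior neural plate, fell from 444.4 ± 6.79 to 229.5 ± 9.48 (SD, n = 2 each), a log2 difference of -0.90 ± 0.10 (SE; limma, adjusted p = 0.000511). Gap43 (-0.90 ± 0.11) and Sox4 (-0.60 ± 0.09) also fell, and Nefl, a neurofilament gene, rose by 0.74 ± 0.12. Of 16 tested members, 1 rose, 4 fell and 11 did not pass, and 2 rose and 4 fell adjusted over the list alone. The list did not pass camera (median -0.11, adjusted p = 0.0884). Of 8 tested germline genes, Ddx4 rose by 0.58 ± 0.13 (adjusted p = 0.0159), Sycp3 fell by 0.65 ± 0.17 (adjusted p = 0.0355) and 6 did not pass. Adjusted over the list alone, 3 rose and 1 fell, and camera gave a median of 0.27 with an adjusted p of 0.532. The call of Sycp3 was lost without knockdown replicate 2 (adjusted p = 0.159) or control replicate 2 (0.0969).

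Targets of p53 and cell cycle inhibitor genes rose more often than they fell. Plk2 rose from 262.7 ± 24.96 to 492.8 ± 19.09 (SD, n = 2 each), a log2 difference of 0.86 ± 0.10 (SE; limma, adjusted p = 0.000855). Phlda3 (0.69 ± 0.09), Perp (0.69 ± 0.11) and Ddit4l (0.94 ± 0.13) also rose. Mdm2, the ubiquitin ligase of p53, rose by 0.66 ± 0.13, while Cdkn1a (p21) had a log2 difference of 0.19 ± 0.12 (adjusted p = 0.295) and Cdkn1b (p27) was the 1 member that fell (-0.80 ± 0.21, adjusted p = 0.0324). Those 3 were chosen after their values were seen. The call of Cdkn1b was lost without knockdown replicate 2 (adjusted p = 0.0884) or control replicate 2 (0.141). Of 23 tested members, 13 rose, 1 fell and 9 did not pass, with 15 and 1 adjusted over the list alone. The list had the smallest camera p of the 18 (median 0.38, adjusted p = 2.01e-05). The adjusted p was 0.431 with an estimated correlation.

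Of 22 tested mitosis genes, 4 passed the test, and of 26 replication genes 2, where 14.4% of all tested genes passed. In the mitosis list 1 rose, 3 fell and 18 did not pass, with the same 1 and 3 adjusted over the list alone (median -0.05, camera adjusted p = 0.0884, and 0.0456 without the filter). Ccnf rose by 0.32, and Top2a (-0.33), Birc5 (-0.30) and Nusap1 (-0.29) fell, although each lost its call without knockdown replicate 2 or control replicate 1. Birc5 also lost its call without control replicate 2, and Nusap1 without knockdown replicate 1. Tk1, a thymidine kinase of S phase, fell by 0.54 ± 0.08 on the log2 scale (limma, adjusted p = 0.00361), and Gmnn by 0.38, a call lost without knockdown replicate 2 (0.0908). In the replication list 0 rose, 2 fell and 24 did not pass, also adjusted over the list alone. For the replication list the median was 0.01, the mean was -0.02 and camera pointed down (adjusted p = 0.337), so the median differed in sign from the other measures.

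In the stress and unfolded protein response list, members moved both ways. Atf4, the transcription factor of the amino acid response, fell from 1610.0 ± 172.5 to 1019 ± 61.0 (SD, n = 2 each), a log2 difference of -0.65 ± 0.09 (SE; limma, adjusted p = 0.00219). Asns, asparagine synthetase, fell by 0.55 ± 0.08, and Hmox1, the heme oxygenase of the oxidative stress response, rose by 0.90 ± 0.14. Of 23 tested members, 6 rose, 7 fell and 10 did not pass, with 7 and 8 adjusted over the list alone. The median was 0.01, the mean was -0.10 and camera pointed down (adjusted p = 0.227), so the median differed in sign. With the mean of all probe sets, Atf4 no longer passed (log2 difference -0.14, adjusted p = 0.472), where the mean takes in a probe set below the filter at 13.05 against 5.65 signal units. Another probe set, above the filter but of a kind that can bind several transcripts and not part of that mean, fell by 0.98 (adjusted p = 0.0174 with every probe set tested by itself).

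Among glycolysis and hypoxia genes, Pfkp, a phosphofructokinase, fell by 0.74 ± 0.10 (limma, adjusted p = 0.00203) and Ero1a rose by 0.66 ± 0.10 on the log2 scale. Of 24 tested members, 3 rose, 5 fell and 16 did not pass, with 4 and 7 adjusted over the list alone. This list missed the threshold of camera (median -0.13, adjusted p = 0.0884). It passed with the mean of all probe sets (0.0187) and without the filter (0.0447). Of 19 tested cholesterol synthesis genes, 0 rose, 2 fell and 17 did not pass, also adjusted over the list alone. Lss, lanosterol synthase, and Idi1 fell by 0.50 ± 0.10 and 0.31 ± 0.08. A dimmer Lss probe set above the filter gave only -0.03 (limma, adjusted p = 0.929 with every probe set tested by itself). Another, below the filter, gave -0.435. The cholesterol list was lower relative to the other tested genes with camera (median -0.16, adjusted p = 0.0387), a call lost with adjusted p = 0.431 with an estimated correlation and 0.148 with the spike-in scaling, where the median was 0.16. It was also lost with adjusted p = 0.104 with the mean of all probe sets, 0.0669 without the intensity trend, 0.099 with fry, 0.131 without knockdown replicate 1 and 0.066 without control replicate 1. Without knockdown replicate 2, Lss (adjusted p = 0.0558) and Idi1 (0.119) no longer passed. Idi1 also lost its call without each of the other arrays in turn (0.0528 to 0.0889).

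Of 11 tested interferon response genes, Irf1 fell by 0.57 ± 0.10 and Bst2 (tetherin) by 0.51 ± 0.10 on the log2 scale (limma, adjusted p = 0.00761 and 0.00938). None rose and 9 did not pass, with 1 rise and 2 falls adjusted over the list alone. The list did not pass camera (median -0.13, adjusted p = 0.0884), and passed with the spike-in scaling (0.0474).

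Markers of fibroblasts, the other cell type that ES cell cultures can hold, rose in part. Vim, an intermediate filament gene that ES cells also express, rose from 530.7 ± 37.1 to 1159 ± 9.05 (SD, n = 2 each), a 2.14-fold rise (SE of the log2 difference 0.08; limma, adjusted p = 9.54e-05). S100a6 (1.18 ± 0.11), Cald1 (0.94 ± 0.11) and, chosen after their values were seen, Thbs1 (1.11 ± 0.13) and Ccn1 (0.69 ± 0.14) rose, and the fibronectin gene Fn1 fell by 0.70 ± 0.08. The collagen genes Col1a1, Col1a2 and Col3a1 lay below the filter, with mean knockdown signals of 10.95, 22.95 and 20.2 against 12, 18.8 and 8.75 in the control. Of 15 tested members, 5 rose, 1 fell and 9 did not pass, with 10 and 3 adjusted over the list alone. The list rose with camera (median 0.36, adjusted p = 0.00868). The adjusted p was 0.437 with an estimated correlation and 0.092 when genes below the filter were included.

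**Figure D3:**
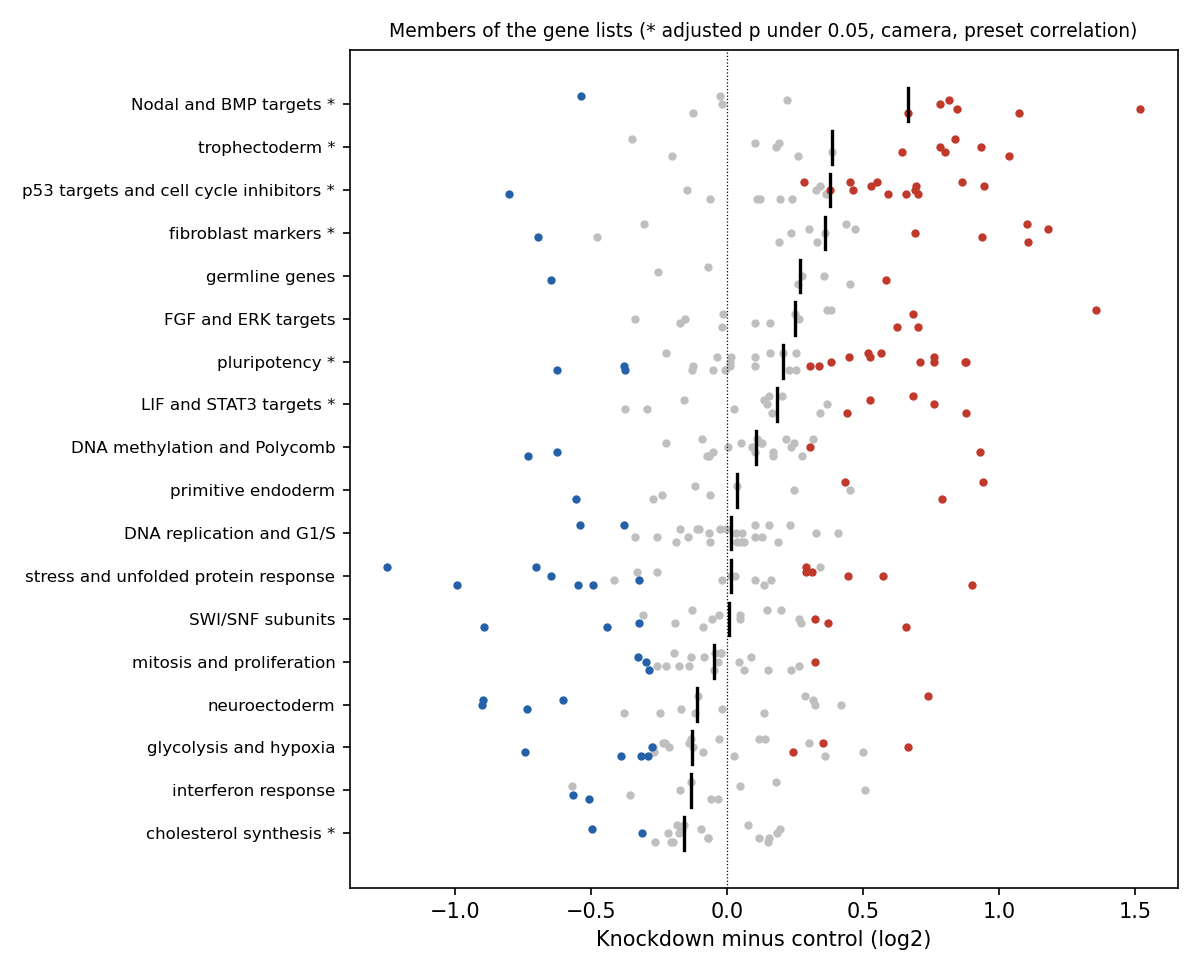
Log2 difference (knockdown minus control) of the tested members of each gene list, with a point per gene, a bar at the list median and an asterisk where camera's adjusted p was under 0.05 with the preset correlation. The p53 target list has its median at 0.38 and the cholesterol synthesis list at -0.16.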

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

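The test of RNA degradation was written after its values had been seen, the spike-in scaling was added after the spike-ins had been seen, the 2-fold count was tested after the scaling test on all changed genes had been read, and the other tests here were written before their own results but after the changed genes were known. Signals outside the main comparison were found in probe sets without a single gene and in the control probe sets.

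Of 1033 probe sets above the filter with no gene or several genes, 90 passed the limma test with every probe set tested by itself, 46 higher and 44 lower in the knockdown. Of these, 52 had no gene and 38 had several. The largest change was in a probe set annotated to Gm4027, BB287469 and Eif1a, with a mean of 513.8 against 48.9 signal units (log2 difference 2.95, adjusted p = 1.12e-05). The hybridisation spike-ins were lower on the knockdown arrays by a log2 difference of -0.31, and 17 of their 18 probe sets were lower on both knockdown arrays than on both control arrays.

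More genes rose than fell, 729 against 398. Unequal RNA degradation is argued against by the 3' to 5' ratios, whose group means differed by at most 1.02-fold. Scaling stays open for the whole set, since 51.0% of the changed genes rose with median centring, between the bounds of 50% and 60% set for and against it, and 97.9% with the spike-in scaling. For changes of 2-fold or more, at least 79.5% of these genes rose with median centring or quantile normalization, above the bound of 60%. Those methods moved the median log2 difference of the tested genes only from 0.04 to -0.01 and 0.01. Shifts that small could hardly reverse changes of 2-fold, so this test does not exclude a larger difference in scale. A wide rise among small changes may come from the scale of the arrays, and the lower level of Brg1 itself remains open as a biological cause.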

How the results depend on the processing

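The crossed replicate block and the spike-in scaling were chosen after seeing the data. Smarca4 stayed lower and past the threshold in all alternatives run for it. With the spike-in scaling its log2 difference shrank from -0.89 to -0.57 (limma, adjusted p = 0.046). With that scaling, falls of Top2a (log2 difference 4e-04), Birc5 (0.026), Nusap1 (0.0361), Idi1 (0.0093) and Ldha (0.037) changed sign without passing the test, as did Hmgcs1 (0.1291), Sqle (0.1136) and Sox2 (0.1009), not called in either fit, and many other named falls lost their call. With the mean of all probe sets the SWI/SNF and the DNA methylation and Polycomb lists, not called in either fit, changed direction (adjusted p = 0.915 each). Pou5f1, also uncalled, had -0.0415 with median centring and -0.0528 to 0.0699 with an array left out, 2 of these values below 0. For the named genes and those chosen later, 1308 values kept direction and side of the threshold under the alternatives that keep all arrays, 111 lost the call and 22 gained it, 9 reversed, and 389, 61, 4 and 2 did so with an array left out. The robust fit was not run for the lists, as camera has no such option. Where no value is named, the cause of a change was not tested, and dim genes are limited by signal over background.

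The 1127 changed genes became 433 without the filter; in a check added later, adjusting the filtered fit for all genes on the array gave 792 and adjusting the unfiltered fit over the filtered genes alone 665, so the number of tests and the variance fit (9.67 and 6.31 total degrees of freedom) both lowered it. The count was 1775 at an adjusted p under 0.10, and 601 to 1171 with an array left out. The replicate number as a block gave 1187 genes, of which 1060 are among the 1127. Deviations of same-numbered arrays from their group means had a weak negative correlation across genes (-0.14), and the crossed block gave 1478. Apart from the FGF and ERK list, the block changed no list call. The 85 genes of 2-fold or more became 157 and 39 with the smaller and larger pseudocount, 53 with the stricter filter, 141 with every probe set by itself, 482 at 1.5-fold and 202 with spike-in scaling. Quantile normalization gave 651 rises and 439 falls, and spike-in scaling 1414 and 30.

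The 7 changed lists became 4 without the intensity trend, 12 at 0.10, 0 with an estimated correlation and 3 to 8 with an array left out. With an estimated correlation the adjusted p was 0.431 for pluripotency, Nodal and BMP, trophectoderm, p53 and cholesterol, 0.467 for LIF and STAT3 and 0.437 for fibroblast markers. That test has few residual degrees of freedom here, so these losses may reflect low power. They may also come from a preset correlation too small for these lists, which would make the main camera p-values too small. Without the intensity trend the adjusted p was 0.0653 for pluripotency, 0.0729 for LIF and STAT3 and 0.0669 for cholesterol. With the stricter filter it was 0.0617 for LIF and STAT3 and 0.264 for Nodal and BMP. Without the filter it was 0.146 for trophectoderm, 0.092 for fibroblast markers, 0.0456 for mitosis and 0.0447 for glycolysis. With the mean of all probe sets it was 0.104 for cholesterol, 0.0347 for FGF and ERK and 0.0187 for glycolysis. With spike-in scaling it was 0.0379 for FGF and ERK, 0.0474 for interferon and 0.148 for cholesterol. FGF and ERK had 0.0447 with median centring and 0.043 with the replicate block. The fry p was 0.109 for LIF and STAT3 and 0.099 for cholesterol. At 0.10, FGF and ERK (0.0585) and the neuroectoderm, mitosis, interferon and glycolysis lists (0.0884 each) passed. With an array left out, the range was 0.00485 to 0.0796 for pluripotency, 0.00432 to 0.212 for LIF and STAT3, 0.00265 to 0.0796 for Nodal and BMP, 0.00725 to 0.254 for FGF and ERK and 0.0148 to 0.131 for cholesterol.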

Other observations

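The 5 lists of amino acid, formative, lysosomal, 2-cell and cytoskeletal genes tested here and the list of fibroblast matrix genes were written after the changed genes had been seen, the 5 leaving out members already seen in the lists and largest changes, the error was added to the rule of the cross-hybridisation test after its result was seen, and the genes named as examples were chosen after their values were seen. A list of amino acid synthesis, amino acid transport, tRNA charging and other ATF4 target genes had 29 tested members. Of these, 0 rose, 11 fell and 18 did not pass, with a median log2 difference of -0.29. The camera p was 4.54e-08 (2.27e-07 adjusted over the 5 lists), and 0.0251 with an estimated correlation (0.126 adjusted). The changed genes were known when the 5 lists were written. Their camera p-values therefore describe the lists and give no independent support. Mthfd2, an enzyme of mitochondrial folate metabolism, fell by 0.63 ± 0.08 (SE; limma, adjusted p = 0.00154), Phgdh, the entry enzyme of serine synthesis, by 0.46 ± 0.08 and Tars, a threonyl-tRNA synthetase, by 0.48 ± 0.09. With the spike-in scaling the list median was 0.03, and Mthfd2 (adjusted p = 0.284), Phgdh (0.636) and Tars (0.595) no longer passed.

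Of 16 tested genes of formative pluripotency, the state between naive ES cells and primed epiblast, 1 rose, 4 fell and 11 did not pass, with a median of -0.20 (0.10 with the spike-in scaling). The camera p was 0.00427 (0.00712 adjusted over the 5 lists) and 0.156 with an estimated correlation (0.39 adjusted). Lef1 fell by 0.81 ± 0.14 (SE; limma, adjusted p = 0.00566), Sall2 by 0.44 ± 0.12 and Zic5 by 0.49 ± 0.13, and Pls3 rose by 0.45 ± 0.12. Lef1 kept its call without each array in turn but not with the spike-in scaling (adjusted p = 0.0619). Sall2 lost its call without each array in turn, and Zic5 without knockdown replicate 1 or control replicate 1. Pls3 lost its call without knockdown replicate 1, knockdown replicate 2 or control replicate 2.

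Lysosomal genes gave 4 rises and 2 falls in 38 tested, with a median of 0.11 and a camera p of 0.267 (0.316 adjusted over the 5 lists). The bound written against a rise, a p over 0.05, was set wrongly, since such a p does not exclude a smaller rise, so this stays open.

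AF067061 and Usp17la rose from control signals below the filter level. A wider set of genes of the 2-cell stage embryo could account for this. The 7 of them on the array had a median log2 difference of 0.49 and a camera p of 0.00132 (0.0033 adjusted over the 5 lists). With an estimated correlation the camera p was 0.255 (0.425 adjusted). Only 3 of the 7 reached the filter, fewer than the 5 required of a list. Camera was therefore run over all genes on the array, unlike for the other lists it was adjusted with. The rest of the 7 lay below the filter level in both groups, near the floor. Arg2, Sp110 and Zfp352, the 3 that reached the filter, had mean control signals below its level, so the sizes depend on the pseudocount. Arg2 rose by 1.32 ± 0.18 (adjusted p = 0.0017) and Sp110 by 1.13 ± 0.23 (adjusted p = 0.0126), and Zfp352 had 0.49 ± 0.17 (adjusted p = 0.0913). Cross-hybridisation of a single probe set cannot be told apart from this, since 1 other probe set of the Usp17 family was higher by 1 or more, at 1.09 ± 0.29 (SE), which does not exceed that bound by its error. Its control signals of 15.3 and 1.2 lay below the filter level, and it is also of a kind that can bind several transcripts. A further probe set of the family was higher by 0.67 but lay below the filter level on all arrays. Effects of the hairpin on other genes were not tested, with 1 hairpin per target.

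The fibroblast marker list rose while Fn1 fell. The mean signal of Col1a1, Col1a2 and Col3a1 rose by 0.772% of the rise in Vim, under the bound written beforehand against fibroblast cells in the knockdown cultures. That bound was wrong, since it sets signals of different probe sets against each other from an assumed profile and the 3 collagens lay below the filter in both groups, so the test is void. A list of fibroblast matrix genes, with these collagens among 12 on the array, had a median log2 difference of -0.05 and a camera p of 0.861. Of the 12, 10 lay below the filter in both groups, Thy1 had -0.48 (limma, adjusted p = 0.108) and Col5a1 0.44 (adjusted p = 0.0785). Fn1 is 1 gene and already had a control signal of 1509.8, so its fall does not decide against fibroblast cells as the cause. The matrix genes moved both ways and most lie near the floor, where they exclude nothing. Fibroblast cells therefore cannot be told apart from a change within the ES cells. A wider set of cytoskeletal SRF and YAP targets gave 4 rises and 1 fall in 19 tested, with a camera p of 0.316, which is also its value adjusted over the 5 lists. The bound written against it, a p over 0.05, was also set wrongly, as for the lysosomal genes, so a smaller rise may still exist.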
